A study of Homo sapiens with 6 samples.

How the data were processed

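Messenger RNA was sequenced from HepG2-hCAR cells, a clone grown from a single cell of the human hepatocellular carcinoma line HepG2 after lentiviral delivery of a doxycycline-inducible cDNA of human NR1I3, the gene of the constitutive androstane receptor (CAR). There were 6 libraries, 3 from cells given vehicle and 3 from cells given doxycycline at 1 µg/ml, all taken at 72 h. Polyadenylated RNA was selected with oligo(dT) beads and made into strand-specific libraries that incorporate dUTP in the second strand.

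The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, computed by the authors, with 1 column per library. The processing notes of the submitters name FastQC, cutadapt, HISAT2 and StringTie and the genome build GRCh37, without versions, options or an annotation release. Per the labels, no column is pooled. Every one of the 11461 entries is a protein-coding gene, and the smallest value of the larger of the group means was 0.500, so weakly expressed genes and noncoding genes were not analysed here. FPKM is already scaled to the mapped fragments of each library and no counts were used here, so the depth of each library is unknown and no counting interval or detection floor is given. FPKM is also a relative unit, so a change is a change in the share of a library. Start and end of 13 of 13 mitochondrial genes were the same as in GENCODE 29, which places the coordinates on a scale that starts at 1.

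Of the 11461 entries, 10 shared 5 symbols between them. The entry with the highest mean FPKM over all libraries represented each symbol, which left 11456 genes. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 10469 in all, and 987 were not. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), fitted with group as the only term and with a trend of the variance on the mean (lmFit and eBayes). It was two-sided, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p below 0.05. Fold changes given as "fold" are ratios of mean FPKM, and log2 fold changes are differences of mean log2(FPKM + 1), doxycycline minus vehicle, which are smaller than the log2 of the ratio for weakly expressed genes. For the receptor and 4 drug-metabolism or transporter genes an exact two-sided permutation test of the difference of mean FPKM was added, whose smallest possible p with 3 against 3 libraries is 0.1.

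Sets of genes were tested with camera of limma, with its preset correlation between genes of 0.01, on 29 lists of 759 symbols, of which 634 were in the table. A list needed 5 tested members, which 28 lists had. Beside camera with the preset correlation, camera with an estimated correlation, camera on ranks and fry were run. Camera compares a list with all other genes, and fry asks whether the genes of a list move, on balance, in 1 direction. Members were counted over all genes tested and again adjusted over the list alone.

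The comparison, the test, the lists, the alternatives and the rule for the genes named were fixed before the data were examined. The rule names NR1I3, the long-known CAR targets CYP2B6, CYP3A4, UGT1A1 and ABCB1, and the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change without overlap between the groups. It adds up to 4 called members with the largest absolute log2 fold change of each list that camera called, and up to 2 of each other list. The largest increases and decreases named below are ranked by this log2 fold change, so a weakly expressed gene can have a larger ratio and a lower rank. CYP3A4 is not in the table and was not analysed here. Of the genes that the rule names, 1 is not reported here. Other genes named below were chosen after their values were seen, and they are identified as such.

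The alternatives were a pseudocount of 0.1 or 0.5, no filter on low values, a minimum mean FPKM of 5, median-ratio scaling, quantile normalization, limma without the trend, limma with robust moderation, the replicate number as a block, the sum of all entries of a symbol, an adjusted p below 0.01, and leaving out each library in turn. The limit of 0.01 was applied only to the numbers of genes changed, higher and lower, not to single genes or lists. Leaving out the genes that overlap another listed gene on the same strand was added after the data had been seen. Transcript length and GC content, used only to look for trends of the fold change, came from GENCODE 29. The figures were drawn with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 in python 3.11.15.

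The procedure was tested on simulated data of 10469 genes with known changes. It recovered 73.8% of the genes changed by 0.5 on the log2 scale (80 genes), 91.2% of those changed by 1 (80 genes) and 92.5% of those changed by 2 (40 genes). Of its 197 calls, 11 were false (5.58%). Of the 28 lists, camera called only the list that had been shifted, with the preset and with the estimated correlation. The simulated values were drawn independently for each gene. The simulation therefore cannot decide whether the preset correlation suits the measured lists. Its singly changed genes were drawn only from the more strongly expressed genes, and far fewer genes were changed than were called in the measured data. Its noise was normal, without the jumps within a group described below. The shares recovered and false may therefore differ in the measured data.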

Results

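Expression of protein-coding genes was measured by RNA sequencing in HepG2-hCAR cells, a clone of the human hepatocellular carcinoma line HepG2 in which doxycycline switches on a lentiviral cDNA of the human constitutive androstane receptor (CAR). CAR, the product of NR1I3, is a nuclear receptor of hepatocytes that activates genes of drug metabolism. There were 3 libraries from cells given vehicle and 3 from cells given 1 µg/ml doxycycline, a tetracycline antibiotic, for 72 h. In each library 11441 to 11453 of the 11461 listed entries had an FPKM above 0, the FPKM values summed to 204318 to 209372, and the sequencing depth is unknown because the values are already scaled. Across genes, Spearman's rho was 0.980 to 0.983 for the 6 pairs of libraries within a group and 0.952 to 0.957 for the 9 pairs between groups, and genes are not independent replicates. The first principal component carried 58.6% of the variance and separated the groups. The labels do not say whether the 3 libraries of a group came from separate cultures. If they did not, the p-values measure only the spread between these samples, which can be technical.

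The series compares the mRNA profiles of vehicle and doxycycline cells, and so addresses which transcripts differ when the receptor is induced. NR1I3 mRNA rose 99.2-fold, from 3.24 ± 0.290 to 321 ± 8.51 FPKM (mean ± SD, n = 3 libraries per group, as for all values below). The drug-metabolism genes UGT1A1 and CYP3A5 rose 15.2-fold and 9.95-fold. CYP2B6, a long-known CAR target, was lower, at 4.90 ± 0.248 against 6.30 ± 0.626 FPKM, a call that was lost in 5 of 17 alternatives (adjusted p 0.0212 to 0.0818). Of 23 genes of secreted liver proteins and coagulation 20 fell, among them AHSG (fetuin A) from 551 ± 47.8 to 102 ± 8.36 FPKM, and of 23 apolipoprotein and lipoprotein assembly genes 17 fell and 2 rose, with APOC3 falling from 28.4 ± 1.25 to 2.89 ± 0.176 FPKM. Both lists were called by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.0613 and adjusted p = 0.122). FABP1, the liver fatty acid binding protein, fell 78.7-fold, from 33.7 ± 2.76 to 0.428 ± 0.108 FPKM.

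Of 10469 genes tested, 3012 (28.8%) were called, 1593 higher and 1419 lower with doxycycline. Of these, 209 changed at least 2-fold on the log2(FPKM + 1) scale, 102 higher and 107 lower. Over the alternatives this number was 144 (minimum mean FPKM of 5) to 325 (pseudocount of 0.1). In all 3012 called genes the values of the groups did not overlap, as in 4936 of the genes tested (47.1%), where chance gives 10%. The median log2 fold change of all genes tested was 0.01. All cells came from 1 clone, and no library had doxycycline without the inducible receptor, so effects of the antibiotic and of the receptor cannot be separated here. FPKM at NR1I3 does not separate the lentiviral cDNA from the endogenous gene.

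**Figure D1:**
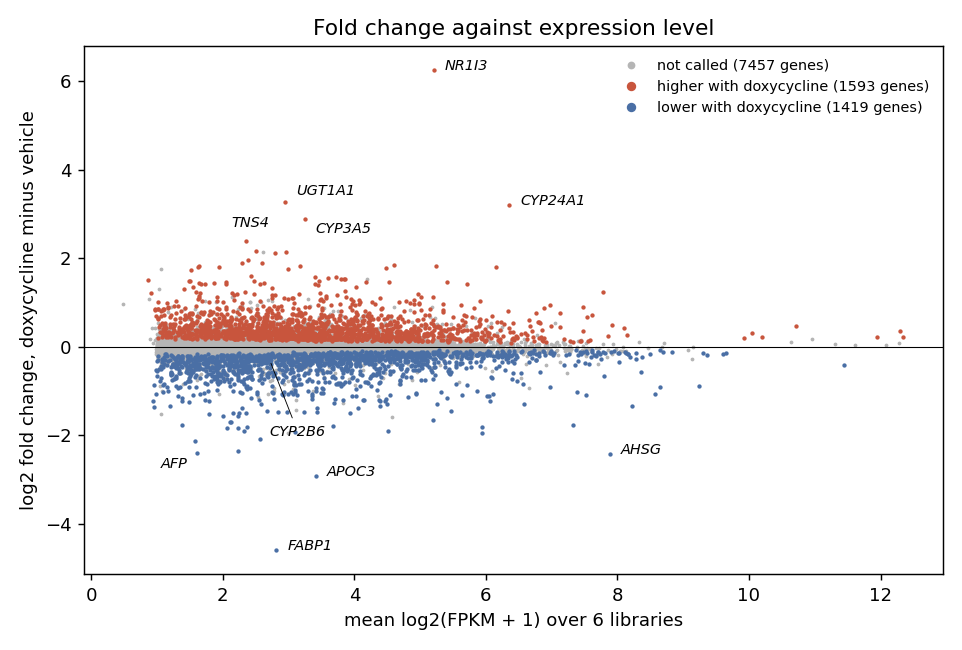
Log2 fold change, doxycycline minus vehicle, against the mean log2(FPKM + 1) of each of the 10469 genes tested. Called genes are coloured, 1593 higher and 1419 lower, and NR1I3 stands highest, at 6.25.

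NR1I3 lies on chromosome 1 of GRCh37 at 161199456 to 161208092 on the minus strand (ENSG00000143257). Its log2 fold change was 6.25 (SE 0.05, adjusted p = 2.4e-07), all 3 doxycycline libraries were above all 3 vehicle libraries, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. UGT1A1, the enzyme that conjugates bilirubin (chromosome 2, 234668894 to 234681945), rose from 1.51 ± 0.243 to 22.9 ± 0.592 FPKM (log2 fold change 3.26, adjusted p = 1.09e-05). UGT1A1 shares its last exons with the nested UGT1A genes, and the sum of the 8 listed UGT1A genes was 9.51-fold higher, at 49.9 ± 7.61 against 5.25 ± 0.964 FPKM, though this sum was not tested. CYP3A5, a drug-oxidizing cytochrome P450 (chromosome 7, 99245817 to 99277621), rose from 2.50 ± 0.290 to 24.9 ± 1.33 FPKM. ABCB1, the P-glycoprotein efflux pump (chromosome 7, 87132949 to 87342639), rose 1.40-fold, from 20.2 ± 0.565 to 28.3 ± 0.752 FPKM. CYP2B6 (chromosome 19, 41497204 to 41524303), which has a near-identical copy that was not analysed here, had a log2 fold change of -0.31 (adjusted p = 0.0272), and its adjusted p ranged from 0.0212 to 0.0818 over the alternatives. The CYP2B6 call ended with the replicate number as a block (adjusted p = 0.0816), without vehicle replicate 2 (0.0707) or 3 (0.0583) and without doxycycline replicate 2 (0.0755) or 3 (0.0818).

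**Figure D2:**
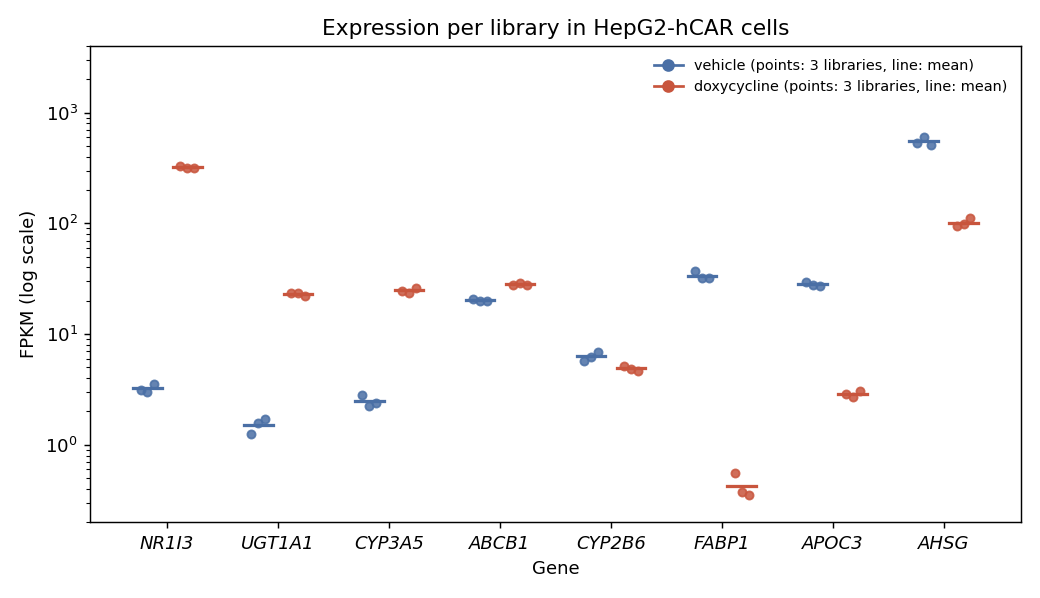
FPKM of 8 genes on a log axis, with 1 point per library and a line at the mean of the 3 libraries of each group. NR1I3, UGT1A1, CYP3A5 and ABCB1 were higher with doxycycline, and CYP2B6, FABP1, APOC3 and AHSG were lower.

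The list of CAR and PXR target genes holds genes activated by CAR or by the related pregnane X receptor. Most are genes of drug metabolism and transport, but some, such as TSKU, are not. The list was called higher (camera adjusted p = 1.03e-05, and adjusted p = 0.122 with an estimated correlation). Of its 25 genes 17 were in the table and tested, and the rest, CYP3A4 among them, were not analysed here. Of its 17 tested members 12 rose and 3 fell, and adjusted over the list alone 13 rose and 3 fell. Besides UGT1A1 and CYP3A5, the largest increases were in TSKU, a secreted protein, from 11.7 ± 0.247 to 46.6 ± 15.4 FPKM, and in EPHX1, microsomal epoxide hydrolase, from 31.1 ± 1.93 to 84.8 ± 0.422 FPKM. The members that fell besides CYP2B6 were the carboxylesterase CES2 (6.95 ± 0.227 to 3.82 ± 0.480 FPKM) and the flavin monooxygenase FMO5 (16.6 ± 0.692 to 8.85 ± 0.215 FPKM), both chosen after their values were seen.

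Ranked by log2 fold change, the genes with the largest increases after NR1I3 and UGT1A1 also included CYP24A1, the enzyme that inactivates vitamin D. CYP24A1 (chromosome 20, 52769988 to 52790512) rose 9.56-fold, from 26.0 ± 0.959 to 248 ± 8.57 FPKM (adjusted p = 9.34e-07). TNS4, a focal adhesion protein, rose 8.59-fold, from 1.24 ± 0.0597 to 10.7 ± 0.714 FPKM. ISM1, a secreted protein, rose 6.53-fold to 11.04 ± 0.854 FPKM, and ANGPTL1, an angiopoietin-like secreted protein, rose 5.77-fold to 13.4 ± 0.412 FPKM. LOXL4, a lysyl oxidase of the extracellular matrix, rose 5.65-fold to 15.3 ± 0.0565 FPKM. CXCL8, the chemokine interleukin 8, rose 5.65-fold to 9.33 ± 1.26 FPKM, and CD3D, a subunit of the T cell receptor complex, rose 5.50-fold to 8.46 ± 1.51 FPKM. Among the genes with the largest decreases were AFP, the fetal liver protein alpha-fetoprotein (18.8-fold lower, 0.320 ± 0.0650 FPKM with doxycycline), and IGSF1, an immunoglobulin superfamily membrane protein (12.4-fold lower, 0.421 ± 0.0908 FPKM). ADH6, an alcohol dehydrogenase, was 5.53-fold lower, UPK3A, a uroplakin, was 5.92-fold lower, and PLA2G12B, a phospholipase-like secreted protein, was 4.68-fold lower.

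Secreted liver proteins and coagulation factors fell as a group (camera adjusted p = 1.63e-14, and adjusted p = 0.0613 with an estimated correlation). Of 23 tested members 20 fell, and 22 did when adjusted over the list alone, with a median log2 fold change of -0.91. AHSG, RBP4, the carrier of retinol (64.2 ± 4.72 to 19.7 ± 3.54 FPKM), and TF, transferrin (149 ± 1.42 to 60.5 ± 4.41 FPKM), were among those with the largest decreases. FGA, the fibrinogen alpha chain, went from 76.5 ± 29.1 to 25.8 ± 1.08 FPKM, with 43.0 FPKM in vehicle replicate 2 against 95.4 and 91.0 in the others, and its call ended without doxycycline replicate 1 (adjusted p = 0.0507, range over the alternatives 1.51e-04 to 0.0507). The members that did not pass were SERPINA1 (187 ± 38.8 and 122 ± 22.5 FPKM), VTN (5.79 ± 0.885 and 4.20 ± 0.474 FPKM) and AMBP (214 ± 11.3 and 222 ± 6.92 FPKM), chosen after their values were seen. Apolipoproteins and genes of lipoprotein assembly fell too (camera adjusted p = 4.58e-08, and adjusted p = 0.122 with an estimated correlation). Of its 23 tested members 17 fell and 2 rose, or 18 and 2 adjusted over the list alone. APOC3, MTTP, the transfer protein that loads lipid onto apolipoprotein B (9.65 ± 0.462 to 1.07 ± 0.127 FPKM), APOH (120.0 ± 5.58 to 30.0 ± 1.65 FPKM) and APOM (22.8 ± 1.11 to 5.88 ± 0.504 FPKM) had the largest decreases. The 2 members that rose, chosen after their values were seen, were APOC1 (69.5 ± 2.34 to 93.1 ± 2.66 FPKM) and LRP1, a lipoprotein receptor (29.6 ± 0.418 to 36.3 ± 1.19 FPKM).

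Transcription factors of the liver were lower as a list (camera adjusted p = 7.38e-04, and adjusted p = 0.131 with an estimated correlation). Of its 20 tested members 9 fell and 1 rose, or 9 and 2 adjusted over the list alone. NR0B2, the repressor SHP, fell from 81.5 ± 4.96 to 40.4 ± 0.774 FPKM, NR2F1 from 6.22 ± 0.0815 to 2.72 ± 0.135 FPKM, and FOXA3 from 13.3 ± 0.341 to 7.27 ± 0.499 FPKM. TBX3 rose from 32.7 ± 0.663 to 44.8 ± 0.0654 FPKM. With a minimum mean FPKM of 5 the call of the list liver transcription factors ended (adjusted p = 0.0933, range over the alternatives 2.54e-04 to 0.131). Markers of fetal liver, progenitors and bile ducts were lower as a list (camera adjusted p = 0.0418, and adjusted p = 0.187 with an estimated correlation). Of its 12 tested members 6 fell and 2 rose, or 7 and 3 adjusted over the list alone. Besides AFP, the growth factor gene IGF2 fell from 25.9 ± 1.41 to 10.98 ± 3.48 FPKM and SPP1, osteopontin, from 172 ± 14.7 to 90.6 ± 6.67 FPKM. SOX4, a progenitor transcription factor, rose 2.53-fold to 12.5 ± 0.733 FPKM. The call of the list fetal liver and progenitor or biliary markers ended with a minimum mean FPKM of 5 (adjusted p = 0.281), quantile normalization (0.212), camera on ranks (0.0533), and without vehicle replicate 1 (0.0769) or doxycycline replicate 3 (0.0697), over a range of 2.19e-04 to 0.281.

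In 3 called lists of lipid and glucose metabolism more members fell than rose. Fatty acid oxidation genes and targets of the receptor PPARA fell as a list (camera adjusted p = 7.07e-03, and adjusted p = 0.185 with an estimated correlation). Of its 19 tested members 6 fell and 1 rose, or 7 and 1 adjusted over the list alone. Besides FABP1, the peroxisomal enzymes EHHADH (10.7 ± 0.567 to 5.41 ± 0.104 FPKM) and ACAA1 (14.4 ± 0.779 to 7.91 ± 0.236 FPKM) fell. ANGPTL4, a lipoprotein lipase inhibitor, was higher (1.31 ± 0.134 to 2.00 ± 0.236 FPKM), a call that ended without vehicle replicate 2 (adjusted p = 0.0534) or doxycycline replicate 1 (0.0560) or 3 (0.0585), over a range of 0.0136 to 0.0585. Fatty acid and triglyceride synthesis genes fell as a list (camera adjusted p = 8.94e-03, and adjusted p = 0.131 with an estimated correlation). Of its 20 tested members 10 fell and 3 rose, or 13 and 4 adjusted over the list alone. DGAT1 (10.2 ± 0.644 to 5.49 ± 0.833 FPKM) and GPAM (18.98 ± 0.276 to 11.2 ± 0.249 FPKM), enzymes of triglyceride synthesis, and PNPLA3, a lipid droplet protein (4.10 ± 0.129 to 1.96 ± 0.219 FPKM), fell. AGPAT2, an acyltransferase, went from 20.7 ± 1.49 to 9.21 ± 5.25 FPKM, and its call ended with robust moderation (adjusted p = 0.0539), without any 1 of the 3 vehicle replicates (0.107, 0.116 and 0.0955), and without doxycycline replicate 1 (0.0771) or 3 (0.117), over a range of 3.31e-03 to 0.117. The call of the list fatty acid synthesis ended with a minimum mean FPKM of 5 (adjusted p = 0.196, range 9.74e-05 to 0.196). Glycolysis and hypoxia response genes fell as a list (camera adjusted p = 6.08e-04, and adjusted p = 0.122 with an estimated correlation). Of its 26 tested members 16 fell and 2 rose, or 18 and 3 adjusted over the list alone. CA9, a carbonic anhydrase induced by hypoxia (23.7 ± 3.40 to 12.9 ± 0.653 FPKM), the glucose transporter SLC2A3 (42.9 ± 1.49 to 25.1 ± 1.803 FPKM) and ANKRD37 (3.73 ± 0.159 to 1.83 ± 0.0873 FPKM) fell. PFKP, a phosphofructokinase, rose from 10.2 ± 0.105 to 19.8 ± 1.70 FPKM.

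Several stress response lists were called. NRF2 target genes, which respond to oxidants, rose as a list (camera adjusted p = 8.28e-04, and adjusted p = 0.131 with an estimated correlation). Of its 22 tested members 12 rose and 3 fell, or 14 and 3 adjusted over the list alone. OSGIN1 (10.1 ± 1.23 to 21.5 ± 0.196 FPKM), the aldo-keto reductases AKR1C3 (34.6 ± 1.17 to 67.0 ± 1.63 FPKM) and AKR1C2 (1.74 ± 0.225 to 3.52 ± 0.0707 FPKM), and GCLM, a subunit of the enzyme that limits glutathione synthesis (11.8 ± 0.466 to 20.4 ± 0.868 FPKM), rose. The 3 members that fell, chosen after their values were seen, were the ferritin light chain FTL (3225 ± 167 to 2429 ± 76.4 FPKM), heme oxygenase HMOX1 (18.2 ± 1.10 to 15.7 ± 0.534 FPKM) and the quinone reductase NQO1 (212 ± 5.23 to 186 ± 4.89 FPKM). Target genes of the tumour suppressor p53 rose as a list (camera adjusted p = 6.07e-04, and adjusted p = 0.294 with an estimated correlation). Of its 26 tested members 11 rose and 1 fell, or 13 and 1 adjusted over the list alone. PMAIP1, a promoter of apoptosis (4.69 ± 0.218 to 11.2 ± 0.475 FPKM), the cell cycle inhibitor CDKN1A (21.8 ± 2.16 to 38.5 ± 2.10 FPKM), PLK3 (2.26 ± 0.301 to 4.37 ± 0.265 FPKM) and TIGAR (3.98 ± 0.196 to 7.17 ± 0.417 FPKM) rose. MDM2, which marks p53 for degradation, fell from 30.9 ± 1.53 to 26.9 ± 1.27 FPKM, a member chosen after its values were seen. Genes of the ATF4 and amino acid stress response rose as a list (camera adjusted p = 1.18e-03, and adjusted p = 0.266 with an estimated correlation). Of its 31 tested members 18 rose and 3 fell, or 18 and 3 adjusted over the list alone. VLDLR, a lipoprotein receptor (0.559 ± 0.0573 to 1.53 ± 0.0846 FPKM), the stress cytokine GDF15 (147 ± 2.89 to 235 ± 5.85 FPKM) and the cystine transporter SLC7A11 (14.3 ± 0.390 to 22.3 ± 1.65 FPKM) rose. ALDH18A1, an enzyme of proline synthesis, fell from 116 ± 2.63 to 66.9 ± 0.859 FPKM. Endoplasmic reticulum stress genes fell as a list (camera adjusted p = 0.0176, and adjusted p = 0.143 with an estimated correlation). Of its 22 tested members 9 fell and 3 rose, or 9 and 3 adjusted over the list alone. The transcription factor XBP1 (36.2 ± 0.520 to 27.3 ± 0.711 FPKM) and the chaperones PDIA4 (188 ± 1.93 to 151 ± 1.74 FPKM) and HSP90B1 (236 ± 5.45 to 193 ± 2.79 FPKM) fell. EDEM1, which directs misfolded proteins to degradation, rose from 14.1 ± 0.732 to 19.1 ± 0.655 FPKM. Quantile normalization ended the call of the list endoplasmic reticulum stress (adjusted p = 0.143, range over the alternatives 3.99e-04 to 0.143).

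Mitosis genes were slightly lower as a list, with a median log2 fold change of -0.11 (camera adjusted p = 7.20e-04, and adjusted p = 0.122 with an estimated correlation). Of 34 members 12 fell and 1 rose, and adjusted over the list alone 13 fell and 1 rose. The phosphatase CDC25C fell from 8.54 ± 0.0645 to 6.21 ± 0.0137 FPKM, the kinesin KIF20A from 20.3 ± 0.350 to 15.2 ± 0.407 FPKM, and CENPF, a kinetochore protein, from 40.2 ± 1.01 to 33.0 ± 1.56 FPKM. PTTG1, securin, was at 39.4 ± 2.39 and 32.4 ± 1.95 FPKM, a call that ended without vehicle replicate 1 (adjusted p = 0.0504) or 2 (0.0549), over a range of 0.0176 to 0.0549. Cytosolic ribosomal protein genes fell as a list, with a median log2 fold change of -0.13 (camera adjusted p = 8.73e-07, and adjusted p = 0.268 with an estimated correlation). Of its 35 members 12 fell, or 19 adjusted over the list alone. RPL3 fell from 207 ± 12.8 to 159 ± 2.92 FPKM and RPL13 from 86.7 ± 1.71 to 75.4 ± 1.05 FPKM. RPS3 was at 37.8 ± 2.83 and 31.9 ± 0.429 FPKM, a call that ended without vehicle replicate 1 or any 1 of the doxycycline replicates (adjusted p = 0.0563, 0.0599, 0.0640 and 0.0720, range over the alternatives 0.0171 to 0.0720). The 13 protein-coding genes of the mitochondrial genome made up 16.6 to 17.4% of the listed FPKM with vehicle and 18.2 to 19.5% with doxycycline. This list, all subunits of oxidative phosphorylation, was higher (camera adjusted p = 2.13e-03, and adjusted p = 0.418 with an estimated correlation), though under quantile normalization the median change of the list mitochondrially encoded OXPHOS was 0.00 and its adjusted p was 0.103, over a range of 1.24e-04 to 0.418. Quantile normalization gives equal ranks equal values, so genes that keep their ranks at the top of every library must show no change. Its result therefore cannot decide whether these abundant genes rose. Of the 13 members of the list 6 rose, or 7 adjusted over the list alone. MT-CYB (1425 ± 88.6 to 1964 ± 62.9 FPKM) and MT-ATP8 (4439 ± 98.8 to 5692 ± 553 FPKM) rose. MT-ATP6 (951 ± 5.07 and 1179 ± 84.6 FPKM) lost its call under quantile normalization (log2 fold change 0.05, adjusted p = 0.415, range 2.27e-03 to 0.415). MT-ND3 (1093 ± 76.8 and 1270.2 ± 47.8 FPKM) turned to -0.05 under quantile normalization (adjusted p = 0.415), and its call also ended with the replicate block (0.0633), without vehicle replicate 2 (0.0895) or 3 (0.0953), and without doxycycline replicate 1, 2 or 3 (0.0756, 0.0918 and 0.0551), over a range of 6.87e-03 to 0.415.

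Mesenchymal and cytoskeletal genes were higher as a list (camera adjusted p = 8.60e-03, and adjusted p = 0.266 with an estimated correlation). Of its 18 tested members 10 rose and 3 fell, or 10 and 4 adjusted over the list alone. ANKRD1, a target of the coactivator YAP, rose 3.52-fold, from 37.5 ± 2.50 to 132 ± 2.22 FPKM. The actin-binding protein TAGLN rose from 2.72 ± 0.371 to 7.41 ± 0.671 FPKM and the integrin ITGB4 from 11.4 ± 0.365 to 20.4 ± 1.5002 FPKM. S100A4, a calcium-binding protein, was at 152 ± 5.08 and 258 ± 72.0 FPKM, and its call ended without the trend (adjusted p = 0.0549), with robust moderation (0.0591), with the replicate block (0.0733), without vehicle replicate 1, 2 or 3 (0.112, 0.125 and 0.108) and without doxycycline replicate 2 or 3 (0.125 and 0.132), over a range of 2.98e-04 to 0.132. Acute phase and NF-kB response genes were called lower (camera adjusted p = 0.0418, and adjusted p = 0.187 with an estimated correlation). Of its 21 tested members 10 fell and 5 rose, or 10 and 6 adjusted over the list alone. The chemokine CCL20 fell from 114 ± 3.13 to 31.8 ± 1.43 FPKM, FGL1, a hepatocyte-secreted protein, from 23.01 ± 0.948 to 10.1 ± 0.116 FPKM, and the protease inhibitor SERPINA3 from 13.9 ± 1.10 to 6.06 ± 0.569 FPKM, while CXCL8 rose. The call of the list acute phase and NF-kB response ended with a minimum mean FPKM of 5 (adjusted p = 0.281), quantile normalization (0.0853), camera on ranks (0.117), without genes overlapping on the same strand, added after the data had been seen (0.241), without vehicle replicate 1 (0.0804) and without doxycycline replicate 3 (0.0694), over a range of 3.71e-04 to 0.281. Markers of cells other than hepatocytes were lower as a list (camera adjusted p = 0.0273, and adjusted p = 0.266 with an estimated correlation). Of its 6 tested members 4 fell and 1 rose, or 5 and 1 adjusted over the list alone. LYZ, lysozyme (550 ± 24.0 to 261 ± 7.33 FPKM), and CD68, a lysosomal protein of macrophages (8.50 ± 0.211 to 5.08 ± 0.618 FPKM), fell. PDGFRB, a growth factor receptor of mesenchymal cells, rose from 0.856 ± 0.0957 to 1.43 ± 0.0327 FPKM. HBA1, a globin, was at 4.16 ± 1.15 and 2.00 ± 0.750 FPKM, and its call ended without vehicle replicate 1, 2 or 3 (adjusted p = 0.0988, 0.0618 and 0.0763) or doxycycline replicate 2 or 3 (0.112 and 0.115), over a range of 4.05e-03 to 0.115. The list non-hepatocyte cell type markers lost its call with no filter on low values (adjusted p = 0.225, range over the alternatives 1.77e-03 to 0.266).

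**Figure D3:**
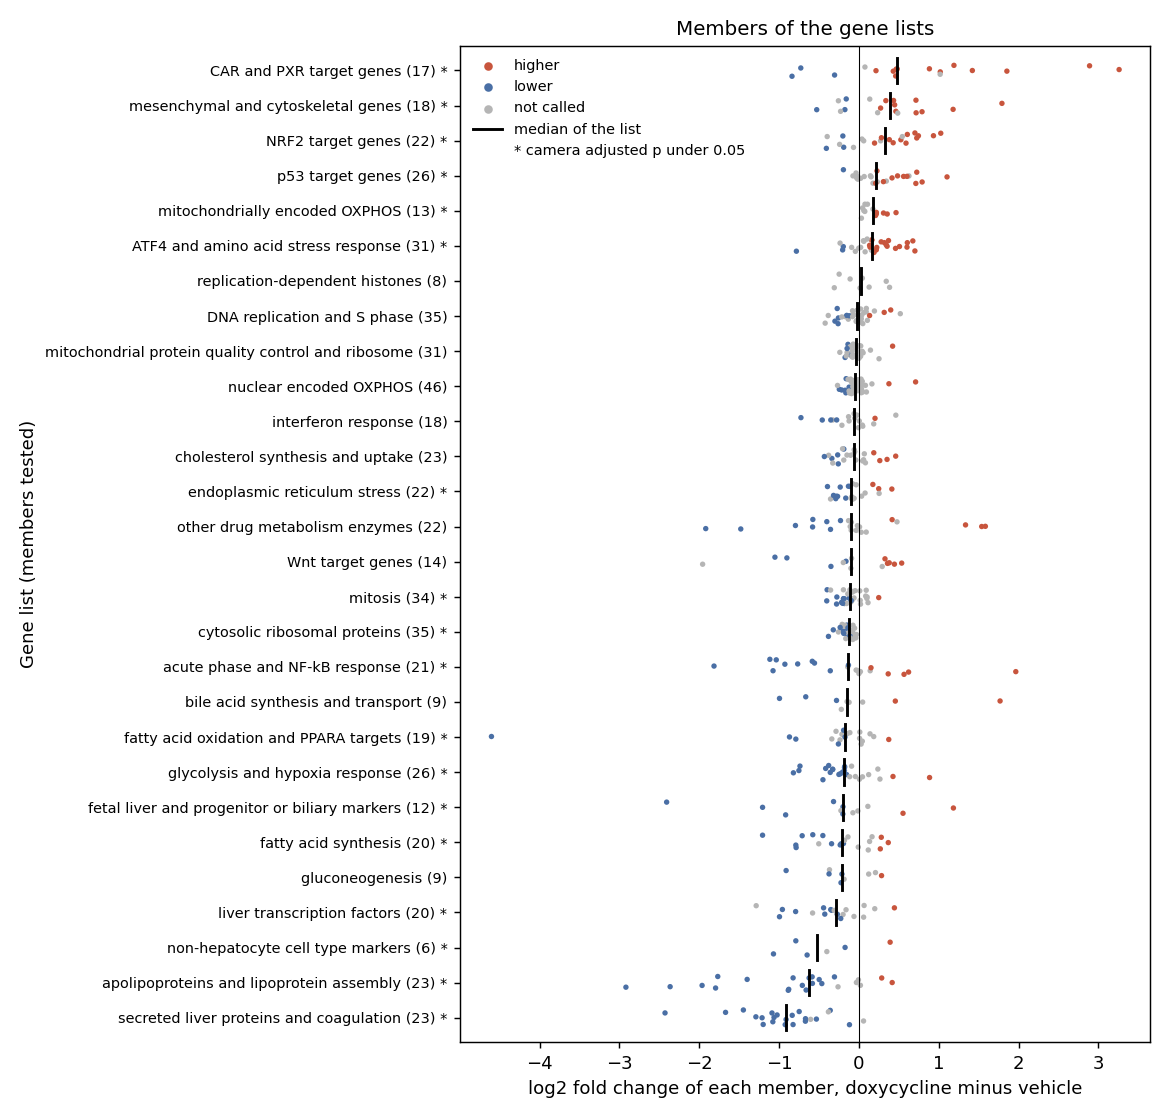
Log2 fold change, doxycycline minus vehicle, of each tested member of the 28 lists, with a black bar at the median of a list and a star at lists with a camera adjusted p below 0.05. Of the 28 lists 18 were called, 6 higher and 12 lower. The mitochondrially encoded list, called higher, had a median of 0.00 under quantile normalization, which gives equal ranks equal values.

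The other 10 tested lists did not pass camera with the preset correlation. Of these, fry called 5, namely other drug metabolism enzymes (adjusted p = 0.00652), bile acid synthesis and transport (0.0337), gluconeogenesis (0.0300), interferon response (0.0246) and Wnt target genes (0.0382). Fry pointed up for the Wnt target genes and down for the others of these 5. Among other drug metabolism enzymes 4 of 22 members were higher and 8 lower (6 and 9 adjusted over the list alone, camera adjusted p = 0.134). SULT1C2, a sulfotransferase, rose from 2.13 ± 0.445 to 8.33 ± 0.389 FPKM while ADH6 fell from 8.76 ± 0.218 to 1.59 ± 0.175 FPKM. Among genes of bile acid synthesis and transport 2 of 9 were higher and 3 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.265). SLC51B, a subunit of the basolateral bile acid exporter, rose 3.61-fold, from 11.2 ± 1.14 to 40.4 ± 2.38 FPKM. For gluconeogenesis the counts were 1 higher and 4 lower of 9 (2 and 5 adjusted over the list alone, camera adjusted p = 0.314). IGFBP1, an insulin-repressed binding protein, was lower at 296 ± 65.0 against 551 ± 53.7 FPKM, and pyruvate carboxylase PC at 9.18 ± 0.455 against 12.2 ± 0.652 FPKM. For cholesterol synthesis and uptake they were 4 higher and 5 lower of 23 (4 and 6 adjusted over the list alone, camera adjusted p = 0.364). The sterol carrier STARD4 rose (6.78 ± 0.233 to 9.71 ± 0.348 FPKM) and PMVK, an enzyme of the mevalonate pathway, fell (11.99 ± 0.902 to 8.62 ± 0.634 FPKM). DNA replication and S phase genes gave 3 higher and 6 lower of 35 (the same adjusted over the list alone, camera adjusted p = 0.396). Cyclin CCNE2 (1.39 ± 0.165 to 2.14 ± 0.0904 FPKM) and the checkpoint protein CLSPN (7.22 ± 0.223 to 9.23 ± 0.184 FPKM) rose. Nuclear encoded OXPHOS genes gave 2 higher and 6 lower of 46 (2 and 5 adjusted over the list alone, camera adjusted p = 0.115). The complex I subunits NDUFV2 (26.4 ± 0.221 to 43.7 ± 0.290 FPKM) and NDUFC2 (47.1 ± 1.67 to 61.4 ± 1.67 FPKM) rose. Mitochondrial protein quality control and ribosome genes gave 1 higher and 4 lower of 31 (1 and 3 adjusted over the list alone, camera adjusted p = 0.184). The elongation factor GFM1 rose (7.85 ± 0.801 to 10.8 ± 0.259 FPKM). The chaperonin HSPD1 was lower (384 ± 11.5 to 341 ± 7.43 FPKM), but under quantile normalization it was called higher, with a log2 fold change of 0.10 (adjusted p = 4.91e-04, range over the alternatives 4.91e-04 to 0.0423). Interferon response genes gave 1 higher and 4 lower of 18 (the same adjusted over the list alone, camera adjusted p = 0.254). USP18, a negative regulator of interferon signalling, fell from 5.46 ± 0.108 to 2.91 ± 0.257 FPKM. OAS1, a sensor of double-stranded RNA, was at 3.02 ± 0.185 and 1.94 ± 0.426 FPKM, a call that ended without vehicle replicate 1, 2 or 3 (adjusted p = 0.0637, 0.0818 and 0.0645) or doxycycline replicate 2 (0.0722), over a range of 0.0118 to 0.0818. Wnt target genes gave 5 higher and 4 lower of 14 over all genes and adjusted over the list alone (camera adjusted p = 0.946). Their median (-0.10) and mean (-0.18) log2 fold changes were negative where camera and fry pointed up. The transcription factor SP5 (43.2 ± 0.790 to 20.4 ± 1.69 FPKM) and the Wnt inhibitor DKK1 (25.1 ± 1.22 to 12.96 ± 0.485 FPKM) fell. Of 8 replication-dependent histone genes, limma called 0, over all genes and adjusted over the list alone, and 1 had an unadjusted p below 0.05 (camera adjusted p = 0.960, fry adjusted p = 0.802). The median log2 fold change of these 8 genes was 0.03, positive where camera pointed down. Of all 20 tested genes with a HIST symbol, grouped after their values were seen, 2 rose and 6 fell, with a median of -0.16 (camera adjusted p = 0.717, and adjusted p = 0.992 with an estimated correlation). The list of targets of the aryl hydrocarbon receptor AHR had only 4 tested members and was not tested as a list. Its members UGT1A6 (0.561 ± 0.0838 to 4.24 ± 0.793 FPKM) and the amino acid transporter SLC7A5 (109 ± 0.468 to 126 ± 2.87 FPKM) rose, NQO1 fell, and TIPARP was at 4.64 ± 0.494 and 5.28 ± 0.569 FPKM, all chosen after their values were seen.

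With an estimated correlation between genes camera called 0 of the 28 lists, with a smallest adjusted p of 0.0613 and 9 lists at an unadjusted p below 0.05. In some called lists the estimate was above the preset 0.01, as in p53 target genes (0.26). In others it was below, as in mitosis (0.00199) and fatty acid synthesis (-0.0407), whose calls ended too (camera adjusted p = 0.122 and 0.131). For mitosis and fatty acid synthesis a larger correlation between members therefore cannot account for the lost call, and its cause was not tested. All 18 lists called by camera also passed fry, which called 23. Fry does not compare a list with other genes, and 28.8% of all genes tested were called. Passing fry therefore does not show that a list moved more than other genes.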

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

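Leaving out genes that overlap another listed gene on the same strand was chosen after the data had been seen, and all other alternatives in this part were planned. Of the 101 genes named by the rule, 88 were called under every alternative run, 12 lost the call under at least 1 and 2 changed direction. MT-ND3 is among both the 12 and the 2, and the limit of 0.01 was not applied to these genes. The log2 fold change of NR1I3 stayed between 6.21 and 6.59. Of 18 called lists, 11 kept the call under every alternative except the estimated correlation. The number of genes changed went from 3012 to 2343 with the replicate number as a block, and to 2309 to 2378 when 1 library was left out. Whether like-numbered libraries belong together is not known. The correlations of the deviations were 0.015, -0.032 and 0.092 for like-numbered libraries and -0.098 to 0.084 for unlike-numbered ones. Each alternative that left the limit on the adjusted p at 0.05 kept at least 71.9% of the 3012 calls among the genes it tested. With an adjusted p below 0.01, 1636 genes were called, 875 higher and 761 lower, by construction of the stricter limit. With a pseudocount of 0.1, 325 genes changed at least 2-fold instead of 209, since a smaller pseudocount widens the log2 differences of weakly expressed genes. With an estimated correlation camera called 0 lists, with 9 at an unadjusted p below 0.05, against 23 for fry, and over the other alternatives the number of lists was 13 to 19. Under quantile normalization the log2 fold change of MT-ND3 was -0.0516 and that of HSPD1 was 0.102, past the threshold in the opposite direction (adjusted p = 4.91e-04), and 15 of the 3012 called genes changed sign in all, and the cause was not tested. The Wnt target genes, whose median and camera direction differ in sign, had a median of -0.0964 and a negative direction of camera without the trend, with the block and on ranks, and -0.1004 without overlapping genes, and leaving out 1 library gave -0.144 (without doxycycline replicate 2) to -0.0138 (without vehicle replicate 2), with a negative direction of camera also without vehicle replicate 1 (-0.130). The histone genes had a median of 0.0283 and a positive direction with the block and with fry, and -0.0348 (without doxycycline replicate 1) to 0.0850 (without doxycycline replicate 2) with 1 library left out, with a positive direction without vehicle replicate 1 (0.0685) or doxycycline replicate 2 or 3 (0.0850 and 0.00629). Fry pointed up for the Wnt target genes. For neither the Wnt list nor the histone list was the cause tested. Robust moderation has no counterpart in camera and was not run for the lists. The sequencing depth is unknown, so what it limits cannot be stated.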

Other observations

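The tests of library scaling, of CYP2B6 and of gene families by symbol were chosen after the results were seen, as were the genes named in this part. Single genes that rose with doxycycline were the inhibitory SMAD7 (5.23 ± 0.187 to 10.4 ± 0.820 FPKM, n = 3 per group) and SMAD6 (2.68 ± 0.125 to 4.70 ± 0.181 FPKM), SMAD9 (2.31 ± 0.0943 to 6.73 ± 0.390 FPKM), and the transcription regulator ID3 (60.8 ± 0.523 to 90.1 ± 1.57 FPKM). Of the 8 tested SMAD genes 4 rose, but the family did not pass (camera adjusted p = 0.183, and adjusted p = 0.992 with an estimated correlation). ATOH8, a helix-loop-helix transcription factor, rose 7.26-fold, from 0.648 ± 0.0503 to 4.71 ± 0.174 FPKM. CDH1, the epithelial adhesion protein E-cadherin, rose 4.98-fold, from 2.16 ± 0.184 to 10.7 ± 1.96 FPKM. The proteases FURIN (12.9 ± 0.493 to 37.3 ± 0.553 FPKM) and TMPRSS2 (2.63 ± 0.198 to 8.72 ± 0.0602 FPKM), the receptor NRP2 (3.78 ± 0.182 to 15.9 ± 0.287 FPKM) and the transcription factor GATA2 (3.33 ± 0.185 to 13.5 ± 0.128 FPKM) rose as well.

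Other genes, picked singly and not counted as a group, fell. SERPINA6, the carrier of corticosteroids, fell from 43.1 ± 0.868 to 10.7 ± 0.689 FPKM, the glucose transporter SLC2A2 from 34.3 ± 0.527 to 13.4 ± 1.04 FPKM, and ASGR1, the asialoglycoprotein receptor, from 58.6 ± 2.49 to 23.4 ± 1.603 FPKM. The liver pyruvate kinase PKLR fell from 6.90 ± 0.348 to 1.43 ± 0.114 FPKM, and PLA2G2A, a secreted phospholipase, from 474 ± 25.2 to 189 ± 34.2 FPKM. Of 178 families of genes that share a symbol root, the serpins of clade A had the smallest camera adjusted p (1.24e-05, and adjusted p = 0.992 with an estimated correlation), with 7 of 8 members lower. Heat shock cochaperones of the DNAJB family had 5 of 8 members higher but did not pass (camera adjusted p = 0.0573). MYC had 3.20, 23.4 and 36.4 FPKM in the vehicle libraries and 3.19, 2.90 and 2.99 FPKM in the doxycycline libraries, and FOXA2 had 9.01, 33.0 and 30.9 FPKM against 8.66, 7.99 and 7.62 FPKM, and neither was called.

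The lower level of secreted liver protein genes was set against trends of the fold change with expression level, transcript length and GC content. After these trends were removed over 10436 genes, the median log2 fold change of the 23 genes was -0.917 (bootstrap SE 0.120) against -0.913 before, and 10000 random lists matched on level had medians of -0.179 to 0.230, which argues against such trends as the whole cause. Under median-ratio and quantile scaling the highest median was also -0.917. Median-ratio scaling could hardly have changed it, since the median log2 fold change of all genes tested was already 0.01. The values therefore show a fall of the list relative to other genes, and a change in total mRNA was not tested. A response to doxycycline itself stays open, since 0 doxycycline libraries lacked the induced receptor and the antibiotic and the receptor cannot be told apart. A response of the cells to the receptor stays open as well, as a hypothesis that was not tested apart from the antibiotic.

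Some abundant genes jumped within a group: of 3881 entries with a mean FPKM of at least 10, 114 had a highest value at least 2 times the lowest within a group, as YWHAH with 45.9, 23.2 and 46.7 FPKM in the vehicle libraries and 49.8, 49.7 and 22.7 FPKM in the doxycycline libraries. Of the 114, 8 were called. The odds of a jump were higher for genes that overlap another listed gene on the same strand (odds ratio 2.87, 95% interval 1.58 to 4.94, Fisher's exact test p = 3.92e-04), so shared reads may account for part of the pattern, but 97 of the 114 overlap no such gene. For these 97, reads shared with a listed gene on the opposite strand are argued against, with an odds ratio of 0.733 (95% interval 0.397 to 1.27). Overlaps with genes that are not listed, such as noncoding genes, were not tested on either strand. A single library behind most of the jumps is argued against too. The library most often the odd one, vehicle replicate 1, was so in 23.7% of jumps (upper 95% limit 32.6%). It was the odd one in 27 jumps, against 14 for vehicle replicate 2 and 14 for vehicle replicate 3. A smaller excess of jumps in vehicle replicate 1 therefore stays open, and what made the other genes jump was not found.

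CYP2B6 was not higher although NR1I3 rose. If a constant amount of reads from near-identical copies had hidden a rise, the doxycycline values would lie at or above the vehicle values, but the highest doxycycline value was 0.904 of the lowest vehicle value. A failure of induction in some libraries is argued against by the lowest doxycycline value of NR1I3, which was 88.5 times the highest vehicle value. A fall in reads from a near-identical copy, which is not in the table, stays open, as does a real decrease of CYP2B6, whose log2 fold change was -0.36 to -0.24 over 17 alternatives, 5 of which ended the call.

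Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes changed as the real grouping, which is the real grouping itself with 3012 genes, against at most 3 for the others. The splits are too few to give a share below 0.05.

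MROH2A, the next listed gene downstream of UGT1A1 on the same strand, was higher too (0.0770 ± 0.0612 to 2.04 ± 0.0980 FPKM, adjusted p = 3.48e-05). HJURP, which lies beyond MROH2A and overlaps its end on the opposite strand, rose as well (15.6 ± 2.18 to 24.9 ± 2.62 FPKM, adjusted p = 8.24e-03), but is not adjacent to UGT1A1 and is outside the test that follows as a partner of either gene. A hypothesis is that neighbouring genes tend to change together across the genome. Over 8988 pairs of adjacent tested genes that do not overlap, Spearman's rho of the log2 fold changes was 0.101 (one-sided permutation p = 0.001, the smallest that 1000 permutations can give). It was 0.147 for pairs within 10 kb on the same strand, 0.120 within 10 kb on opposite strands and 0.0491 for pairs over 100 kb apart, so a weak tendency of this kind may contribute at UGT1A1, and reads that run past the end of UGT1A1 into MROH2A were not tested.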
